A study of Mus musculus with 7 samples.

How the data were processed

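Bulk RNA-seq libraries from the brains of C57BL/6J mice labelled P90 were analysed, 3 labelled noCRS and 4 labelled CRS. Per the labels, total RNA came from neurons of the medial prefrontal cortex that project to the lateral habenula (labelled mPFC-LHB projection neurons). Per the labels' protocols, RNA was extracted with a micro kit and libraries were made with TruePrep DNA Library Prep Kit V2, a transposase kit that does not mark strand. How the neurons were marked and isolated, and how cDNA was made, is not given in the sources used here. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

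The deposited table holds raw counts per gene, as whole numbers, for 55367 genes with exon coordinates. Per the submitters' processing notes, the tools included FastQC, HISAT, HISAT2, featureCounts and DESeq2, with the build GRCm38, and no versions were given. The column names end as the default output names of another aligner, STAR, do, so which aligner stands behind the counts was not settled. Of the 55367 genes, 53252 matched 1 gene of GENCODE M21 (GRCm38) by symbol and chromosome, and 99.3% of those had the same start and end. Coordinates are those of the deposited table, on GRCm38. Reads were not counted here again. Because strand is not marked, reads from a gene and an overlapping partner on the other strand cannot be told apart. Of 115 named genes, 40 share exon sequence with another gene, and 11 share over 10% of their exon length, among them Bdnf, Ccn2, Fgfr3, Hcn3, Lhfpl3, Nwd2, Ppp1r1b, Rarres2, Sox8 and Syt4, whose values are uncertain for that reason. Genes that share sequence with paralogs or pseudogenes, such as ribosomal protein genes, are uncertain, since the handling of multiply aligned reads is not given in the sources used here.

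Library totals ran from 28677703 to 39965667 counts. A floor of 3 counts in 1 library corresponded to 0.0724 to 0.0990 CPM. Over a whole group it corresponded to 0.0286 CPM in noCRS and 0.0224 CPM in CRS, and this group floor was used for lower bounds on fold. Floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. They do not cover spread between libraries. The biological coefficient of variation was 0.919, and 26.75% of tested genes had a 0 in at least 1 library. Over the noCRS libraries, for example, Gabra5 had 258, 0 and 0 counts and Cd68 had 1, 159 and 0. A fold given below as at least a value is therefore a bound on counts, not on expression. No pair of libraries was a duplicate, since the chi-square per gene between 2 libraries was at least 99.0.

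Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, default expression filter, quasi-likelihood test, CRS over noCRS, no covariate), with Benjamini-Hochberg adjustment over 17833 tested genes and a threshold of 0.05. CPM values are TMM-normalised. Log2 CPM used a prior count of 2. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with an inter-gene correlation of 0.01. Adjustment ran over 23 pathway lists and, separately, over 14 of the 15 cell type lists, since the blood cell list had 1 tested member. Each list was tested again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. Members were counted past the threshold over all genes and adjusted over the list alone.

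The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, with at least 5 CPM in the higher group, leaving out predicted models and pseudogenes, to be filled to 10 by unadjusted p where fewer qualified, which was not needed. It added up to 4 members of smallest p in each list past the threshold and in the immediate early, glucocorticoid-responsive, ionotropic glutamate receptor, postsynaptic density and synaptic vesicle lists. It also added the 2 most abundant members of each cell type list, and Fos, Arc, Bdnf, Fkbp5, Nr3c1, Crhr1, Slc17a7, Gad1 and Camk2a. This named 115 genes, 60 of them past the threshold. Other genes named below were chosen after their values were seen. Results of some of these genes are not reported here, though every count includes them. A pair of listed symbols was matched through RefSeq synonyms (Ctgf as Ccn2, Fam19a1 as Tafa1).

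Alternatives were DESeq2 1.42.0, limma-voom with quality weights, 3 other scalings, 2 other filters, removal of mitochondrial and rRNA genes, protein-coding genes alone, 3 other thresholds, each library left out in turn, the replicate number as a block, 1 surrogate variable (sva 3.50.0) and a glial marker score as covariates. Thinning every library to the smallest total was added after seeing the data, as were 2 lists used in the closing section: neuronal structural and RNA-binding genes, and genes that respond to handling. A set of 9 interneuron transcripts was also taken from the planned lists at that point. All 35 splits of the libraries into 3 and 4 were refitted. The alternative for normalised values was not run, because the table holds counts.

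The tests were checked on counts simulated for CRS against noCRS over 17833 genes, with 200 genes changed. edgeR recovered 5.97% of the 67 genes changed 2-fold, 41.8% of the 67 changed 4-fold and 57.6% of the 66 changed 8-fold, and called 2 unchanged genes. DESeq2 recovered 13.4%, 56.7% and 75.8% and called 128 unchanged genes among 225 calls. limma-voom recovered 7.46%, 38.8% and 45.5% and called 1 unchanged gene. Both lists of planted genes were called in the right direction, and 0 of 40 random lists were called. Simulated genes varied independently of each other, so this check does not cover lists of correlated genes. In the real lists the estimated correlation reached 0.567 (oligodendrocytes).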

Results

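Gene expression was measured by RNA-seq in medial prefrontal cortex neurons that project to the lateral habenula, in mice labelled CRS (n = 4 libraries) and noCRS (n = 3 libraries). The series title places the work under chronic stress and depression, and its design text names 1 contrast, CRS against noCRS. The noCRS libraries held 39965667, 28677703 and 30483420 counts and the CRS libraries 33608080, 34685154, 32346275 and 39740623 counts. Between 16938 genes (CRS replicate 2) and 23399 genes (CRS replicate 4) had at least 1 count. Pearson correlations of log2 CPM were 0.786 to 0.822 within noCRS, 0.766 to 0.872 within CRS and 0.714 to 0.83 between the groups. CRS replicate 2 stood apart from the others on the first principal component, which held 30.4% of the variance. Xist had 0 counts in 6 libraries and 10 in CRS replicate 4, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were detected in all 7.

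Neuronal transcripts were higher in the CRS libraries, and the genes that fell included markers of oligodendrocyte precursors. Snap25, a SNARE protein of synaptic vesicle fusion (chromosome 2, 136713453 to 136782428), measured 158 ± 57.7 CPM (SD, n = 3) in noCRS and 2747 ± 611 CPM (SD, n = 4) in CRS, a 17.4-fold difference. Fos, an activity-induced transcription factor, rose 3.19-fold, from 3224 ± 326 to 10281 ± 3478 CPM. C1ql1, a precursor marker, fell from 204 ± 36.2 to 54.3 ± 15.7 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 410 of 17833 genes differed, 369 higher and 41 lower in CRS. All 410 had groups that did not overlap, as did 16.9% of tested genes against 5.71% from chance. At least a 2-fold change was seen in 332 of the higher and 33 of the lower genes, and 51 of the higher genes had 0 counts in every noCRS library.

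The count depended on which libraries entered the test: it was 223, 142 and 180 without noCRS replicates 1, 2 and 3, and 191, 187 and 184 without CRS replicates 1, 3 and 4. DESeq2, given all 55367 genes of the table with its own filter of low counts, called 1631 genes. limma-voom, on the 17833 genes of the edgeR test, called 639. Higher genes made up 90% of the calls with TMM factors and 79.5% when libraries were scaled by total counts alone, a scaling that moved the median log2 fold change of all genes by -0.16.

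The libraries held abundant glial transcripts in both groups. Apoe, an astrocyte lipoprotein, measured 5099 ± 154 and 3529.5 ± 814 CPM (edgeR adjusted p = 0.217). Against that background the excitatory cortical neuron markers had a mean log2 CPM of 0.17 ± 0.60 in noCRS and 4.95 ± 0.28 in CRS. In that list 4 of 12 members rose (10 of 12 adjusted over the list alone), and all 12 had positive fold changes, with a median log2 fold change of 4.30. The list passed camera (adjusted p = 4.81e-14) and held with an estimated correlation (adjusted p = 0.037).

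Among the excitatory markers that rose were Nrgn, a calmodulin-binding protein of dendrites (13.6 ± 1.36 to 201 ± 38.9 CPM, log2 fold change 3.89 ± 0.23 SE, edgeR adjusted p = 0.000386), and Neurod6, a transcription factor of cortical pyramidal neurons (1.03 ± 1.53 to 193 ± 51.7 CPM, adjusted p = 0.0161). The Neurod6 call was lost without noCRS replicate 1 (adjusted p = 0.0626), and its noCRS mean was 0.148 CPM without noCRS replicate 2. Sv2b, a vesicle glycoprotein, rose from 3.84 ± 4.21 to 168 ± 48.7 CPM (noCRS mean 1.41 CPM without noCRS replicate 1), and the remaining riser was Snap25. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, measured 0.20 ± 0.35 CPM in noCRS and 10.1 ± 2.79 CPM in CRS, with no overlap but short of the threshold (adjusted p = 0.188), and all its noCRS counts were in replicate 1. Camk2a measured 7.20 ± 5.62 and 15.5 ± 6.86 CPM (adjusted p = 0.589; noCRS mean 4.03 CPM without noCRS replicate 1).

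**Figure D1:**
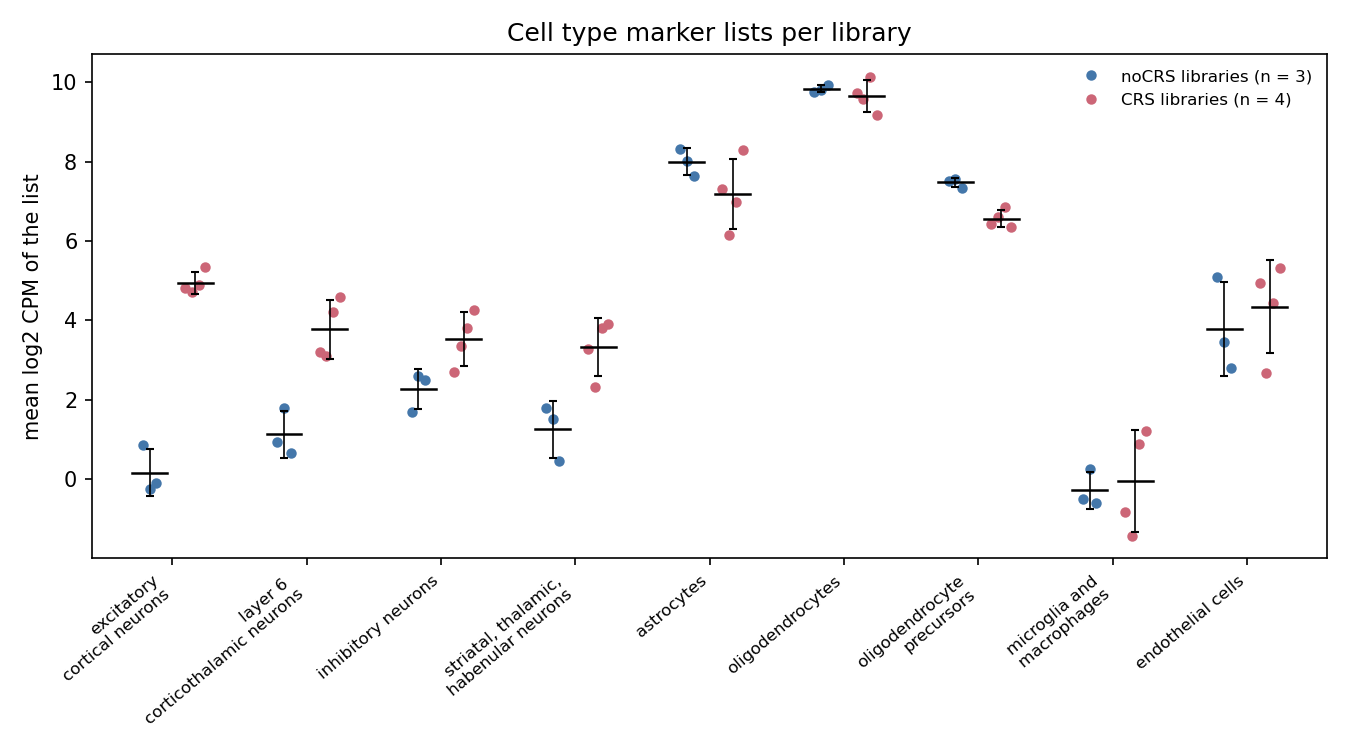
Mean log2 CPM of 9 cell type marker lists (y axis) in each noCRS library (blue) and CRS library (red), with the group mean (wide bar) and SD (error bar). The excitatory cortical neuron list sits near 0.17 in noCRS and 4.95 in CRS, while the oligodendrocyte list sits at 9.83 and 9.65.

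Markers of other neuron types were mixed. In the layer 6 corticothalamic list, 1 of 7 tested members rose (2 adjusted over the list alone), Ccn2, a secreted matrix protein also known from deep-layer neurons. Ccn2 had 0 counts in noCRS and 23.7 ± 8.14 CPM in CRS, at least 820.3-fold over the noCRS group floor. That list passed camera (adjusted p = 0.000889) but not with an estimated correlation (adjusted p = 0.091). In the list of striatal, thalamic and habenular neurons, 1 of 8 rose (2 over the list alone), Slc17a6, the glutamate transporter typical of thalamic and habenular neurons. Slc17a6 had 0 counts in noCRS and 12.5 ± 6.15 CPM in CRS, at least 424.7-fold over the noCRS group floor. This list had a camera adjusted p of 0.0407 (adjusted p = 0.184 with an estimated correlation), a call lost without noCRS replicate 2 or 3 or CRS replicate 1, 3 or 4 (adjusted p up to 0.157).

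The layer 5 extratelencephalic list, whose cells project below the cortex, did not pass camera (adjusted p = 0.326) but was called as higher by fry (adjusted p = 0.000959), with 1 of 9 members risen (2 adjusted over the list alone), Crym, from 3.53 ± 2.99 to 99.45 ± 33.8 CPM. The Crym call was lost without noCRS replicate 3 or CRS replicate 1 (edgeR adjusted p up to 0.0894), and its noCRS mean was 1.99 CPM without noCRS replicate 2. The upper-layer list did not pass (adjusted p = 0.79), and edgeR called 0 of its 7 members (0 over the list alone), with 0 at an unadjusted p below 0.05, 0 by DESeq2 and 0 by limma-voom. The layer 5 intratelencephalic list did not pass either (adjusted p = 0.359): edgeR called 0 of 7 members (3 adjusted over the list alone, 2 of them higher), with 4 at an unadjusted p below 0.05, 3 by DESeq2 and 1 by limma-voom. For the upper-layer list the median log2 fold change (-0.40) and the mean difference of log2 CPM (0.10) had opposite signs. Inhibitory neuron markers went both ways and did not pass camera (adjusted p = 0.271), though fry called the list as higher (adjusted p = 0.0238), with 2 of 14 risen and 1 fallen (4 and 1 adjusted over the list alone). Gad1, which makes GABA, rose from 25.7 ± 4.08 to 97.4 ± 43.1 CPM, and Sst, a peptide of interneurons, rose from 2.54 ± 0.29 to 168 ± 156 CPM (CRS mean 91.4 CPM without CRS replicate 2). The Gad1 call was lost without any library other than CRS replicate 2 (edgeR adjusted p up to 0.136).

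**Figure D2:**
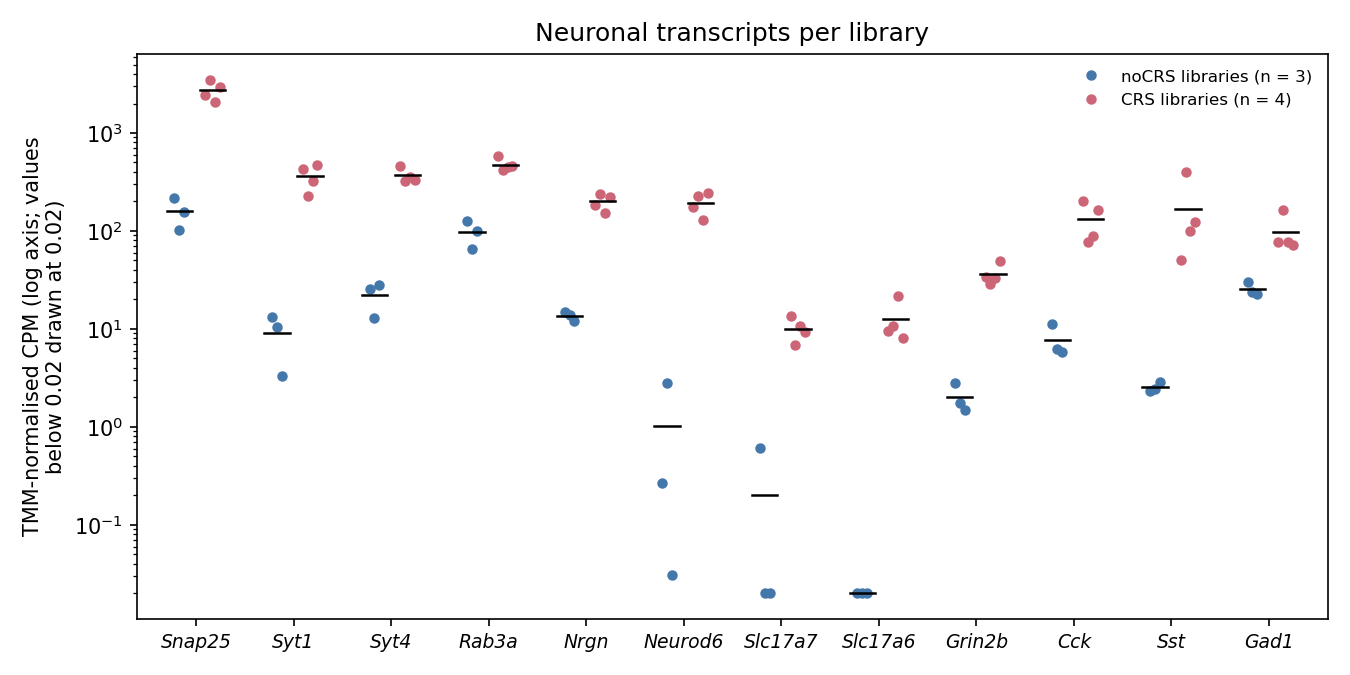
TMM-normalised CPM (y axis, log scale) of 12 neuronal genes in each noCRS library (blue) and CRS library (red), with the group mean as a bar, and values below 0.02 drawn at 0.02. Snap25 lies near 158 CPM in noCRS and 2747 CPM in CRS, and Slc17a6 was at 0 in all 3 noCRS libraries.

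Of the synaptic vesicle release genes 10 of 32 rose (18 adjusted over the list alone) and 0 fell, and 29 had positive fold changes, with a median log2 fold change of 1.58. Camera gave an adjusted p of 3.53e-13, and the call held with an estimated correlation (adjusted p = 0.0365). The members of smallest p were Snap25 (log2 fold change 4.12 ± 0.33 SE, edgeR adjusted p = 0.00127), the calcium sensor Syt1 (9.002 ± 5.14 to 364 ± 111 CPM), Syt4 (22.1 ± 8.09 to 370.1 ± 64.7 CPM) and Rab3a, a vesicle GTPase (97.6 ± 30.6 to 475 ± 69.98 CPM). Syt4 shares 14.5% of its exon length with a gene on the other strand.

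Of the GABA receptor subunits 3 of 14 rose (5 over the list alone). Camera gave an adjusted p of 0.0371, a call lost with an estimated correlation (adjusted p = 0.556) and without noCRS replicate 2 or 3 or CRS replicate 1 or 4 (adjusted p up to 0.142). Of the postsynaptic density genes 3 of 28 rose (4 over the list alone): the scaffold Dlg1 (45.9 ± 8.46 to 149 ± 26.3 CPM), the ATPase Nsf (90.5 ± 17.5 to 370 ± 159 CPM) and the AMPA receptor auxiliary subunit Cacng3, which had 3 counts over noCRS, all in replicate 1, and 38.3 ± 19.8 CPM in CRS. The Nsf call was lost without any library other than CRS replicate 2 (edgeR adjusted p up to 0.152) and that of Dlg1 without noCRS replicate 2 (adjusted p = 0.0501). That list passed camera (adjusted p = 0.0145) but not with an estimated correlation (adjusted p = 0.556).

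Of 22 sodium, calcium and HCN channel genes, 1 rose (4 over the list alone, with 1 lower): Scn2b, a sodium channel beta subunit (14.0 ± 8.70 to 160 ± 94.3 CPM). Its camera adjusted p was 0.0459 (adjusted p = 0.266 with an estimated correlation), and the call was lost without noCRS replicate 1 or 2 or CRS replicate 1 or 2 (adjusted p up to 0.214). The Scn2b call was lost without noCRS replicate 2 or 3 (edgeR adjusted p up to 0.123), and its noCRS mean was 9.31 CPM without noCRS replicate 1. The ionotropic glutamate receptors did not pass (adjusted p = 0.44), with 1 of 17 risen (2 higher and 3 lower adjusted over the list alone). Grin2b, an NMDA receptor subunit, rose from 2.01 ± 0.68 to 36.2 ± 8.99 CPM, while Grin2a (3.59 ± 1.83 and 20.98 ± 14.3 CPM), Grin2c (15.7 ± 4.16 and 4.01 ± 1.82 CPM) and Grik1 (47.4 ± 15.6 and 17.0 ± 8.49 CPM) were short of the threshold.

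Potassium channels did not pass camera (adjusted p = 0.567), with 2 of 30 risen (2 higher and 1 lower adjusted over the list alone), Kcnma1 (11.3 ± 1.34 to 38.4 ± 11.1 CPM) and Kcnip4 (4.57 ± 3.17 to 43.7 ± 8.58 CPM). Neither did monoamine and acetylcholine receptors (adjusted p = 0.113), with 1 of 18 risen (1 over the list alone), the muscarinic receptor Chrm2 (0.03 ± 0.05 to 11.9 ± 7.42 CPM), nor neurotrophin and growth factor signalling (adjusted p = 0.48), with 1 of 20 risen (1 higher and 2 lower over the list alone). Kcnma1, Kcnip4 and Chrm2 were named after their values were seen, and their calls were lost with edgeR adjusted p up to 0.174: Kcnma1 without any single library, Chrm2 without any other than noCRS replicate 3 and CRS replicate 2, and Kcnip4 without noCRS replicate 2 or CRS replicate 1, 3 or 4. Without noCRS replicate 3 the noCRS mean was 2.80 CPM for Kcnip4 and 0 for Chrm2. For metabotropic glutamate receptors (camera adjusted p = 0.542) edgeR called 0 of 6 members (0 over the list alone), as did DESeq2 and limma-voom, with 0 at an unadjusted p below 0.05. For axon guidance genes (camera adjusted p = 0.44) edgeR called 0 of 36 (3 adjusted over the list alone), with 6 at an unadjusted p below 0.05, 5 by DESeq2 and 0 by limma-voom.

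Neuropeptide genes were among those that rose. Their list shares Sst, Npy, Vip and Cnr1 with the inhibitory neuron list, so the lists are not independent. In the list of neuropeptides, opioid and cannabinoid signalling, 4 of 20 rose (13 over the list alone, with 2 lower), with a median log2 fold change of 4.12, and the camera call (adjusted p = 6.17e-10) held with an estimated correlation (adjusted p = 0.0365). Cck, a cortical peptide, rose from 7.76 ± 2.98 to 133 ± 60.6 CPM. Crhbp, which binds the stress peptide CRH, had 0 counts in noCRS and 17.5 ± 14.0 CPM in CRS. That was at least 598-fold over the noCRS group floor (10.6 CPM and at least 362-fold without CRS replicate 2). Adcyap1, which encodes the peptide PACAP, was at least 509-fold over that floor at 14.7 ± 11.2 CPM (9.53 CPM and at least 331-fold without CRS replicate 1). The call of Sst was lost without noCRS replicate 1 or 2, and that of Adcyap1 without noCRS replicate 2 or CRS replicate 1 (edgeR adjusted p up to 0.0552 and 0.053). The CRH receptor Crhr1 measured 0.31 ± 0.54 and 3.08 ± 4.01 CPM (adjusted p = 0.768), with a noCRS mean of 0 without noCRS replicate 2 and a CRS mean of 1.30 CPM without CRS replicate 1.

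Immediate early genes, which neurons and other cells induce within minutes of stimulation, were higher in CRS: 24 of 26 had positive fold changes and 5 rose (17 adjusted over the list alone). Nr4a2 rose from 24.9 ± 6.34 to 174 ± 62.0 CPM, Nr4a3 from 4.74 ± 0.47 to 61.8 ± 27.8 CPM and Klf4 from 28.4 ± 10.1 to 95.8 ± 20.2 CPM, beside Fos (log2 fold change 1.67 ± 0.30 SE, edgeR adjusted p = 0.0302). The remaining member, Egr3, named after its values were seen, rose from 3.13 ± 2.05 to 30.1 ± 12.8 CPM (noCRS mean 1.955 CPM without noCRS replicate 2). Arc, a synaptic activity gene, measured 35.5 ± 15.7 and 45.2 ± 13.3 CPM (adjusted p = 0.831), and Bdnf, a neurotrophin, 0.58 ± 0.97 and 21.04 ± 14.5 CPM (adjusted p = 0.223), with a noCRS mean of 0.016 CPM without noCRS replicate 3. Camera gave an adjusted p of 2.6e-10 (adjusted p = 0.185 with an estimated correlation). The Fos call was lost without any library other than CRS replicate 2 (edgeR adjusted p up to 0.136), that of Egr3 without any other than noCRS replicate 2 (up to 0.128) and that of Klf4 without any other than noCRS replicate 3 and CRS replicate 2 (up to 0.106).

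**Figure D3:**
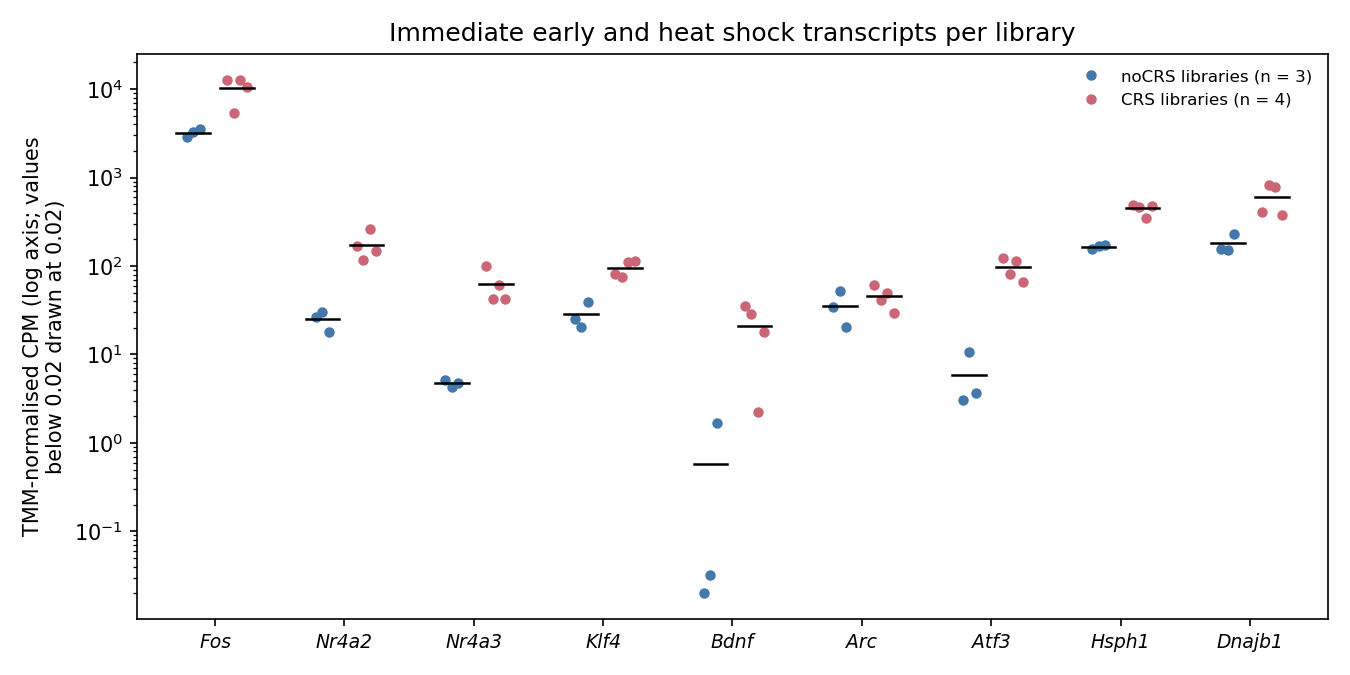
TMM-normalised CPM (y axis, log scale) of immediate early and heat shock genes in each noCRS library (blue) and CRS library (red), with the group mean as a bar, and values below 0.02 drawn at 0.02. Fos lies near 3224 CPM in noCRS and 10281 CPM in CRS, while the groups overlap for Arc.

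Of the heat shock and unfolded protein response genes 4 of 28 rose (7 over the list alone, with 1 lower). These were the stress-induced factor Atf3 (5.84 ± 4.30 to 96.2 ± 27.1 CPM; noCRS mean 3.37 CPM without noCRS replicate 2) and the chaperones Hsph1 (164 ± 9.55 to 447 ± 65.1 CPM), Dnajb1 (180 ± 44.3 to 599.6 ± 239 CPM) and Dnaja1 (192 ± 28.6 to 347 ± 42.6 CPM). The list had a camera adjusted p of 0.00709 (adjusted p = 0.556 with an estimated correlation). The Dnaja1 call was lost without any single library (edgeR adjusted p up to 0.185) and that of Dnajb1 without any other than CRS replicate 4 (up to 0.173).

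No member of the glucocorticoid-responsive list changed by edgeR over all genes (0 of 19; 1 adjusted over the list alone; camera adjusted p = 0.882), with 2 at an unadjusted p below 0.05, 1 called by DESeq2 and 0 by limma-voom. Fkbp5, a cochaperone induced by glucocorticoids, measured 30.5 ± 5.33 and 19.2 ± 15.3 CPM (edgeR adjusted p = 0.779; CRS mean 11.9 CPM without CRS replicate 3), and the receptor Nr3c1 126 ± 21.02 and 145 ± 41.7 CPM (adjusted p = 0.872). Of the same list, Cdkn1a measured 24.0 ± 6.11 and 73.9 ± 25.8 CPM (adjusted p = 0.0528). The median log2 fold change of this list was 0.05 and its mean difference -0.29, camera's direction was down and that of fry up. In simulation edgeR recovered 5.97% of genes changed 2-fold and 41.8% of genes changed 4-fold, so 2-fold changes in single members were mostly not detectable.

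Nuclear oxidative phosphorylation genes had 43 of 44 fold changes above 0 with a median log2 fold change of 0.48, and 3 rose (19 over the list alone, with 1 lower): the electron carrier cytochrome c, Cycs (114 ± 17.1 to 265 ± 68.4 CPM), Ndufa10 (95.9 ± 15.1 to 199 ± 37.5 CPM) and Atp5g1 (109 ± 11.3 to 203 ± 27.1 CPM). The Atp5g1 call was lost without any single library, that of Cycs without any other than CRS replicate 2 and that of Ndufa10 without any other than CRS replicate 3 (edgeR adjusted p up to 0.17). Camera gave an adjusted p of 3.09e-08 (adjusted p = 0.266 with an estimated correlation). Cytosolic ribosomal protein genes passed camera (adjusted p = 0.0414) with a median log2 fold change of 0.22. edgeR called 0 of its 50 members (0 over the list alone), with 6 at an unadjusted p below 0.05, 3 by DESeq2 and 0 by limma-voom. The camera call was lost with an estimated correlation (adjusted p = 0.701), with DESeq2 size factors (adjusted p = 0.0627) and without noCRS replicate 1, CRS replicate 2 or CRS replicate 3 (adjusted p up to 0.837). The 13 mitochondrially encoded genes did not pass (camera adjusted p = 0.567), and edgeR called 0 of them (0 over the list alone), with 2 at an unadjusted p below 0.05, 1 by DESeq2 and 0 by limma-voom.

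Oligodendrocyte precursor markers were lower in CRS. All 9 had negative fold changes, with a median log2 fold change of -0.63, and 4 fell (4 over the list alone). Neu4, a sialidase, fell from 378 ± 39.8 to 131 ± 31.3 CPM, the proteoglycan Cspg4 from 104 ± 16.5 to 45.5 ± 8.94 CPM, and Gpr17, a receptor of committed precursors, from 145 ± 53.1 to 47.4 ± 14.9 CPM, beside C1ql1. The most abundant members over both groups together, Pdgfra (911 ± 236 and 764 ± 219 CPM) and Lhfpl3 (320.1 ± 35.5 and 243 ± 70.3 CPM), did not pass. Camera gave an adjusted p of 0.000182 (adjusted p = 0.106 with an estimated correlation). The calls of Cspg4 and Gpr17 were lost without any single library (edgeR adjusted p up to 0.156 and 0.18), that of C1ql1 without noCRS replicate 2 (0.052) and that of Neu4 without noCRS replicate 3 (0.0506).

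Mature oligodendrocyte markers did not pass as a list (adjusted p = 0.359, median log2 fold change 0.03, mean difference -0.18). Of these 16 genes 1 fell (2 adjusted over the list alone), the lineage factor Sox10 (named after its values were seen), from 127 ± 6.42 to 45.8 ± 12.2 CPM, a call lost without any library other than CRS replicates 1 and 2 (edgeR adjusted p up to 0.0918). Astrocyte markers passed camera as lower (adjusted p = 0.00366, median log2 fold change -0.51), a call lost with an estimated correlation (adjusted p = 0.576) and without noCRS replicate 1 (adjusted p = 0.0565). edgeR called 0 of its 16 members (0 over the list alone), with 5 at an unadjusted p below 0.05, 3 by DESeq2 and 0 by limma-voom. Microglia (camera adjusted p = 0.968), endothelial cells (0.326), pericytes, smooth muscle and fibroblasts (0.326) and ependyma and choroid plexus (0.574) did not pass. edgeR called 0 members of each, over all genes and over the list alone, with 0, 1, 1 and 0 at an unadjusted p below 0.05, 0, 1, 1 and 0 by DESeq2 and 0 by limma-voom. The endothelial list passed without noCRS replicate 1 (adjusted p = 0.0277) and without CRS replicate 2 (adjusted p = 0.0154). Hba-a2 was the only blood cell marker tested, with 0 counts in noCRS and 1.59 ± 1.83 CPM in CRS (edgeR adjusted p = 0.21; CRS mean 0.739 CPM without CRS replicate 4). It was past an unadjusted p of 0.05, which for a list of 1 is the value over the list alone, and was called by DESeq2 but not by limma-voom.

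**Figure D4:**
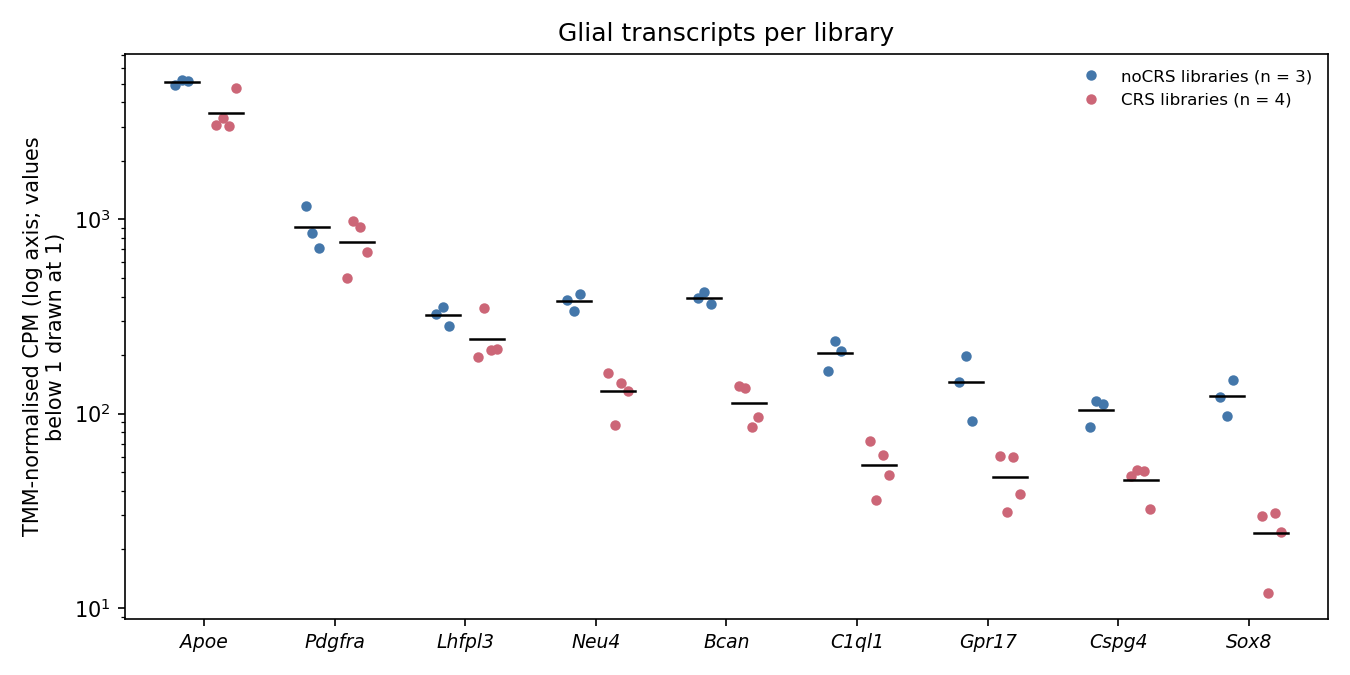
TMM-normalised CPM (y axis, log scale) of 9 glial genes in each noCRS library (blue) and CRS library (red), with the group mean as a bar. Neu4 lies near 378 CPM in noCRS and 131 CPM in CRS, while the groups overlap for Pdgfra and Lhfpl3.

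The 12 largest rises taken by the rule for named genes were all of genes with 0 counts in noCRS: Sla, Ighm, Ccn2, Ipcef1, Mlip, Zmat4, Glt8d2, Cdh9, Slc35f4, Crhbp, Galnt14 and Ptgs2. Their folds over the noCRS group floor ran from at least 560.5-fold (Ptgs2, 16.2 ± 6.94 CPM in CRS) to at least 1025-fold (Sla, 29.4 ± 6.13 CPM). These bounds cover counting error only, so the difference in expression may be smaller. Sla is a Src-like adaptor protein, Ighm the constant region of the immunoglobulin mu heavy chain (28.3 ± 10.9 CPM), Cdh9 a cadherin and Ptgs2 the inducible cyclooxygenase. All 12 kept their call without each library in turn, and without CRS replicate 2 the bound of Ipcef1 moved from at least 702-fold to at least 456-fold. Ccn2 shares 23.2% of its exon length with a gene on the other strand.

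The 12 largest falls were of Sox8, Chst5, Sh3bp4, Pak4, C1ql1, Itpr2, Bcan, Daam2, Acss1, Matn4, Orai1 and Fzd9, with log2 fold changes from -2.34 to -1.65. Bcan, a brain matrix proteoglycan, fell from 393 ± 27.7 to 114 ± 26.8 CPM and was the only 1 of these 12 to keep its call without each library in turn, with edgeR adjusted p up to 0.217 among the others. Sox8, a factor of the oligodendrocyte lineage, fell from 123 ± 26.1 to 24.2 ± 8.66 CPM, a call lost without noCRS replicate 1 or 3 (edgeR adjusted p up to 0.0566), and it overlaps a gene on the other strand, Cerox1, that held 88625 counts. The number of lower genes, 41 with all libraries, was 13, 4 and 7 without noCRS replicates 1, 2 and 3, and 11, 12 and 22 without CRS replicates 1, 3 and 4.

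Cholesterol synthesis genes did not pass camera as a list (adjusted p = 0.113), with 2 of 22 risen (7 adjusted over the list alone), among them the pathway enzyme Hmgcs1 (290.3 ± 53.8 to 656 ± 130 CPM), which shares 12.1% of its exon length with a gene on the other strand and is uncertain for that reason. It was named after its values were seen, and its call was lost without any library other than CRS replicate 4 (edgeR adjusted p up to 0.146). The inflammatory cytokine and NF-kB list (camera adjusted p = 0.44) held 1 riser among 11, Ptgs2 (1 over the list alone), and was called as higher by fry (adjusted p = 0.00987). The lists for oxidative stress response (camera adjusted p = 0.44), interferon response (0.24), circadian clock (0.866) and DNA and histone methylation and acetylation (0.434) did not pass. edgeR called 0 members of each (1, 0, 0 and 0 adjusted over the list alone), with 4, 2, 0 and 3 at an unadjusted p below 0.05, 2, 1, 0 and 0 by DESeq2 and 1, 0, 0 and 0 by limma-voom. The cholesterol list passed without CRS replicate 4 (adjusted p = 0.0483). Median and mean log2 differences had opposite signs for the inflammatory (-0.01 and 0.88), neurotrophin (-0.29 and 0.18), circadian (-0.06 and 0.06), microglial (-0.01 and 0.25) and mitochondrially encoded (0.18 and -0.12) lists.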

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

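Within the 4 CRS libraries, a library was picked out where its gap to the nearest other library was a larger part of the group's range than the 95% critical value of Dixon's test. Chance picks out about 1 in 20 groups; here it was 14 of 114 named genes and 2 of 38 lists. The 3 noCRS libraries were not tested this way.

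CRS replicate 2 was the far library for 6 of these genes and both lists. It was high for Gad1 (162 CPM against 72.5 to 77.8 in the others), Crhbp (38.3 against 8.16 to 12.9 CPM), Lhfpl3 (347.5 against 196 to 214 CPM) and Map3k6 (7.52 against 2.57 to 3.37 CPM). It was low for Itpr2 (16.7 against 45.2 to 50.5 CPM). Its mean log2 CPM was 0.34 for metabotropic glutamate receptors (3.70 to 4.36 in the others) and 1.39 for layer 5 intratelencephalic markers (3.34 to 3.66).

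CRS replicate 4 was low for Cspg4 (32.2 against 48.0 to 51.2 CPM) and Rps3 (227 against 265 to 269 CPM). It was high for Pak4 (17.4 against 12.9 to 13.1 CPM) and Hs3st4 (7.17 against 5.92 to 6.08 CPM). CRS replicate 1 was high for Camk2a (25.7 against 11.1 to 13.5 CPM) and Mlip (24.5 against 18.2 to 19.3 CPM), and CRS replicate 3 was low for Hsph1 (349.6 against 469 to 486 CPM).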

How the results depend on the processing

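Every alternative here except thinning was planned; thinning was chosen after seeing the data. Of the 60 named genes past the threshold, 0 changed sign under any alternative, and 26 stayed past it in all but the block. A change of sign was hardly possible when a library was left out, since the groups of called genes did not overlap. Among the other named genes, 32 of 1083 values changed sign, in no case past the threshold. Counts stayed within 1.5 times of 410 for the other scalings (312 to 388), no filter (350), the 5 CPM filter (442), protein-coding genes (428), removal of mitochondrial and rRNA genes (411), 1 surrogate variable (358), a 2-fold minimum (365) and thinning (417).

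DESeq2, given all 55367 genes with its own filter, so that tool and filter both differed, called 1631 genes (1221 higher, 410 lower), with all 410 genes of the edgeR test among them; in simulation it also called 128 unchanged genes. limma-voom called 639 (117 lower). The glial score as a covariate gave 250 (230 higher, 20 lower). Adjusted p below 0.1 gave 714 (602 higher, 112 lower), and unadjusted p below 0.05 with a 2-fold change gave 1429 (1066 higher, 363 lower), by construction. Lower genes numbered 64 with total-count scaling and 69 with the 5 CPM filter. For these the cause was not tested.

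Without 1 library at a time, 142 to 352 genes were called (138 to 313 higher, 4 to 39 lower), with fewer samples in each test, and 29 of the 60 named calls stayed in all 7 runs. With an estimated correlation 2 pathway lists and 1 cell type list passed, against 9 and 5; the leave-one-out ranges were 7 to 9 and 4 to 6. fry called 6 pathway lists (5 of the 9) and 6 cell type lists (4 of the 5). It did not call GABA receptors, postsynaptic density, sodium, calcium and HCN channels, cytosolic ribosomal proteins or astrocytes, and it added inflammatory cytokines and NF-kB, layer 5 extratelencephalic neurons and inhibitory neurons. Without noCRS replicate 1 the call of astrocytes was lost and endothelial cells passed, as they did without CRS replicate 2.

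Same-numbered libraries did not deviate together (correlations of deviations 0.0153, -0.00319 and 0.0228), and not every sample correlated best with its own number. No pairing by number was therefore seen, though this check cannot show that equal numbers mark nothing shared. With the number as a block and CRS replicate 4 left out, 12 genes were called (12 higher, 0 lower), and 8 pathway and 4 cell type lists passed. edgeR recovered 5.97% of genes changed 2-fold in simulation, so such changes were mostly not detectable.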

Other observations

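The splits of the libraries were planned for the gene count before the data were examined. Their use for lists, thinning, the 6 other tests of explanations and the comparisons given beside them were chosen after the patterns had been seen. The test of immediate early genes was first run on Fos alone against the non-synaptic neuronal genes (difference -0.54, groups overlapping, exact permutation p = 0.143) and was then replaced by the whole list, with the same reading. For interneuron transcripts and for the abundant precursor markers, the requirement of an exact p below 0.05 was added after their values were seen. Under the first version, which asked only that the groups did not overlap, both explanations would have been ruled out. For the handling genes, the requirement that members outside the heat shock list rise too was added after both sets of values were seen. Without it, the full set would have met the prediction for a stronger handling response.

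Neuronal genes outside the synapse were also higher in CRS. Of 24 tested genes for neuronal cytoskeleton, axon growth and neuronal RNA-binding proteins, 11 rose and 0 fell (edgeR), and 22 had positive fold changes, with a median log2 fold change of 1.95. None of the 24 is in another list, and the genes named here were chosen after their values were seen. The calls of Nefl, Rtn1, Rbfox1, Ina and Nefh were lost in some of the 7 runs without 1 library (edgeR adjusted p up to 0.18). Those of Gap43, Stmn2, Stmn3, Dync1i1, Uchl1 and Celf4 held in all 7. Gap43, an axon growth protein, rose from 56.8 ± 14.4 to 482 ± 82.6 CPM, Stmn2 from 18.8 ± 3.58 to 167 ± 47.8 CPM, Dync1i1, a dynein chain of neurons, from 11.25 ± 2.62 to 219.8 ± 34.9 CPM, and Uchl1, a ubiquitin hydrolase, from 14.9 ± 1.78 to 142 ± 1.56 CPM. Mapt measured 148 ± 28.9 and 131 ± 17.0 CPM and Elavl3 43.9 ± 6.72 and 45.6 ± 3.35 CPM, both short of the threshold. Malat1, a nuclear RNA, measured 29787 ± 2414 and 19661 ± 6131 CPM (adjusted p = 0.379).

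The labelled split was the only 1 of the 35 splits of the libraries into 3 and 4 to call as many genes. It called 410, and the highest other split called 0. As 1 split makes 2.86% of 35, the smallest share possible, chance is unlikely for that count but not excluded. For pathway lists, 1 of 35 splits gave as many as 9, and the highest other gave 7, a narrow margin, so chance is not excluded there either. For cell type lists, 4 of 35 splits gave at least 5, and the highest other gave 7, so chance cannot be excluded for that number.

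Neuronal transcripts were higher in CRS while glial transcripts dominated both groups. A difference in library size was ruled out as the source: 99% of the 410 calls remained when all libraries were thinned to the smallest total. A larger share of neuronal RNA in the CRS libraries is a candidate explanation: the non-synaptic neuronal genes were 2.14 log2 units higher (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow). The difference between synaptic vesicle genes and these genes moved by -0.08 between the groups (exact permutation p = 0.83). Its SD among the noCRS libraries was 0.648, so this does not show that the 2 lists moved alike. Excitatory neuron markers did not move in step: they were higher by a further 2.64 log2 units, with no overlap (exact permutation p = 0.0286), so an equal rise of all neuronal genes does not cover them. Whether other cells that express the non-synaptic genes held their rise down was not tested. Regulation within projection neurons at an equal neuronal share would leave interneuron transcripts level. The 9 tested were 1.89 log2 units higher on average with no overlap (two-sided exact permutation p = 0.0571), and 8 had positive fold changes. Their mean goes against it, but the rise was uneven. Log2 fold changes were 6.05 for Sst and 4.59 for Vip, against 0.01 for Pvalb and -2.17 for Dlx2. The planned inhibitory neuron list, which holds these genes, was 1.27 log2 units higher and did not pass camera (adjusted p = 0.271). The groups of the 9 were also close (1.675 in the highest noCRS library, 1.896 in the lowest CRS library), and 2 of 9 passed the threshold. Regulation at an equal neuronal share is therefore at most weakened and not ruled out. A response to the stress itself stays open as well.

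Immediate early genes were higher in the same libraries. Added neuronal RNA as the only source may account for the list average, but that depends on the neuronal genes compared. The immediate early list was 2.12 log2 units higher, the non-synaptic neuronal genes 2.14 and the excitatory neuron markers 4.78. Only the non-synaptic genes, a list added after the data were seen, were used in the test. The difference between the immediate early list and the non-synaptic neuronal genes moved by -0.0134 between the groups (exact permutation p = 0.914). A high p from 7 libraries does not show that the lists moved alike. Single members departed both ways: the log2 fold change was 0.35 for Arc (edgeR adjusted p = 0.831) and 3.70 for Nr4a3. Fos was already at 3224 CPM in noCRS, and its cells of origin were not tested. A stronger response to handling in the CRS libraries cannot be told apart: 12 handling-response genes outside the immediate early list were 1.11 log2 units higher (exact permutation p = 0.0286), but 5 of them, with the 3 past the threshold (Atf3, Hsph1 and Dnajb1), are also in the heat shock list reported above. For the other 7 the difference was 0.495 and the groups overlapped (exact permutation p = 0.114). These 7 were set apart after the values of both sets were seen. Before that, the rule asked for a rise of the 12 alone, and the 12 met it. Both explanations stay open, as does activity induced by the stress, which was not tested separately.

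Oligodendrocyte precursor markers were lower in CRS. Dilution by added neuronal RNA would lower precursor and oligodendrocyte markers alike, but precursor markers moved by -0.735 relative to oligodendrocyte markers (exact permutation p = 0.0286), which argues against it as the whole cause. A lower share of precursors would lower their most abundant markers as far as the rest. The difference between Pdgfra and Lhfpl3 and the rest moved by 0.726 log2 units, with no overlap (two-sided exact permutation p = 0.0571). That cannot count against a lower share, since the pair was ranked as most abundant with the CRS values included. In noCRS alone Neu4 (378 CPM), which is among the rest and fell, was above Lhfpl3 (320 CPM). The groups were also close (2.26 in the highest noCRS library, 2.397 in the lowest CRS library). A lower share of precursors therefore stays open. A change of gene expression within precursors under stress stays open and was not tested.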
